A study of Mus musculus with 1617 samples.

How the data were processed

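Single macrophages were sorted from mouse brain, captured on Fluidigm C1 mRNA sequencing chips and made into Nextera XT libraries, per the labels' protocols, and each of the 1617 samples is 1 cell. The authors deposited 1 table of gene values in TPM, a unit that scales genes by transcript length and sets each cell's total to the same value. RSEM 1.2.19, Seurat and the GRCm38 mouse genome are named in the submitters' processing notes; the aligner, the annotation, the Seurat version and any filter on cells or genes are not given in the sources used here. Column sums of 996167 to 1000000 fit the unit. TPM keeps no record of depth, so reads per cell are unknown, and C1 libraries of this kind carry no molecular identifiers. No strand information is given, so genes that overlap on opposite strands cannot be separated, and values of near-identical copies such as Hspa1a and Hspa1b are uncertain singly. No 2 columns were identical and each column matched 1 sample title.

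Cells were grouped by the age and region that the labels give, in 16 groups. The descriptions name paired-end reads for 436 cells, and the other 1181 are called single-read here; P14 visual cortex held 120 single-read and 150 paired-end cells, which made 17 sets. Comparisons were made within 1 layout, except A2M against adult hippocampus, the layout control and the alternative that set adult against paired-end P14 visual cortex cells. Gaps in the cell numbers of the titles gave 30 title runs, unbroken stretches of 1 source and layout, 29 of them with 10 cells or more; what they stand for is not known, and they were used only as a technical split. All cells entered the means; 1541 held 1000 genes or more and 76 fewer. Since no animal, litter or preparation is named, no p-value or standard error was made from cells. Counts of genes beyond a fold are descriptions, not counts of tested changes.

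For each comparison, log2 of the ratio of mean TPM was taken with a pseudocount of 1 TPM, which understates differences of genes at low levels. A gene counted as measured with a mean of 5 TPM or more in either group. Of 43280 gene names, 39379 (91.0%) matched 1 gene of the GENCODE M21 annotation of GRCm38, from which coordinates were taken; Emr1 is the table's symbol for Adgre1. Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. The lists were homeostatic microglia, disease-associated microglia, cell cycle, inflammatory cytokine and NF-kB, immediate early, interferon response, MHC class II, MHC class I, complement, lysosome and phagocytosis, cholesterol and lipid handling, glycolysis, TGF-beta signalling, macrophage transcription factors, fetal and imprinted, ribosomal protein, sort and sex genes, and markers of border-associated macrophages, monocytes, neutrophils and other cell types. Lilrb4a, listed among the disease-associated genes, has no entry of that name in the table. For each list the median log2 ratio over measured members, the members at least 1.5-fold higher or lower, and the percentile of the median among 10000 random lists of the same size, drawn from 20 bins of mean expression, were computed; the percentile describes these cells and is no p-value.

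Named genes needed a mean of 50 TPM in the higher group, 1 TPM or more in 25% of its cells and the same sign as the difference in mean log2(TPM + 1). Of these, the 10 largest ratios in each direction and up to 4 per list were taken, without mitochondrial, ribosomal protein, predicted and Y-linked genes, pseudogenes and Xist in the ranking. Over 3 regions, genes were ranked by the smallest of the 3 ratios. Up to 5 genes per region were taken from those 1.5-fold above both other regions at P14 and adult. Genes named as the members behind a count, in pairs, or because an alternative changed them were chosen after their values were seen. Some genes that this rule takes are not reported here.

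Shares of cells used a level of 1 TPM and exact Clopper-Pearson 95% intervals; where a share was 0, the limit is that of 3 counts. Intervals and limits cover counting error over cells only. Cells were clustered on log2(TPM + 1) of the 2000 most variable genes with 30 principal components, 15 neighbours and Leiden clustering at resolution 1, and a cluster took the name of the type with the highest share of its fixed markers seen in 50% of the cells. It stayed unnamed with fewer than 3 such markers, with more markers of another type among its leading genes, or with none of the type's markers leading and a median of genes per cell, relative to that of the cell's own set, under 1/3. No doublet caller was run, since such callers are built on molecule counts. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9. The ratio of means was tested on simulated data made from thalamic P14 cells, with 2763 genes. At each of 4 sizes, 50 genes were changed. The median log2 recovered was 2.0 for a 4-fold increase and 1.09 for a 2-fold increase. It was -0.87 for a decrease to 0.5, -2.02 for a decrease to 0.25 and -0.02 over 2563 genes left as they were. Each change was made alike in all cells of 1 random part of a single set. The test therefore checks the calculation, not run effects or means that rest on few cells.

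Alternatives fixed beforehand were pseudocounts of 0.1 and 10 TPM, the difference of mean log2(TPM + 1), no filter on low values, cells with 1000 genes or more, cells with 3 or more of 12 microglia markers, median-ratio rescaling, rescaling without mitochondrial and ribosomal protein genes, each title run left out, title runs weighted equally, paired-end P14 visual cortex cells, P7 in place of adult hippocampus, other levels for shares and regions, and other clustering settings. A further 6 were added after seeing the data: rescaling without Calb1, Pax6, Cp and Smco1, leaving out cells with Calb1 at 100000 TPM or more in the list comparisons and in the regions, leaving out a pair of adult runs with titles beside embryonic ones, P7 against E18.5 in thalamus and visual cortex only, and shares at 100 TPM.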

Results

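The data were single-cell transcriptomes of 1617 macrophages from mouse brain, sorted as CD45, F4/80 and CD11b positive and Ly6C negative, a gate that takes in microglia and other resident brain macrophages. Each cell was captured on a Fluidigm C1 chip and sequenced as its own library. Whole brain gave 146 cells at E12.5, 126 at E16.5 and 221 in the adult. Hippocampus gave 21 cells at E18.5, 34 at P7, 118 at P14 and 66 in the adult, and 83 further hippocampal cells carried the label A2M, whose meaning is not given in the sources used here. Thalamus gave 50, 44, 190 and 99 cells at E18.5, P7, P14 and adult, and visual cortex gave 22, 32, 270 and 95. Values were TPM, transcript levels scaled to a fixed total per cell, over 43280 genes, so each cell summed to about 1000000 and the number of reads behind a value is unknown. A cell held a median of 3528 genes at 1 TPM or more (range 139 to 7068). No animal was named, so each age and region was 1 sample without replicates; cells are not replicates, and no difference was tested. Means are over cells, fold changes are log2 of the ratio of mean TPM with 1 TPM added to each, and "higher" and "lower" in counts of list members mean 1.5-fold or more. Means can rest on few cells: as differences of mean log2 values, where each cell weighs more evenly, 179 of the 240 list and all-gene medians of 1.5-fold or more over all comparisons were smaller by 1.5 times or more or changed sign, and 30 of these changed sign.

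To examine how brain macrophages differed between early and late embryonic stages, whole-brain cells of E16.5 were set against those of E12.5. Genes of homeostatic microglia stood higher at E16.5. Sall1, a transcription factor that maintains microglial identity (chromosome 8, 89027235 to 89044162, minus strand), averaged 85.2 TPM at E16.5 and 11.0 TPM at E12.5 (log2 2.84), and Siglech, a sialic acid-binding lectin, 538 and 115 TPM (2.22). P2ry12, the purinergic receptor that guides microglial processes (chromosome 3, 59216272 to 59262871, minus strand), averaged 1329.7 and 422 TPM (1.65). Of 14 measured homeostatic genes 9 were higher and 0 lower, with a median of 0.95 against 0.18 over all measured genes, at percentile 99.99 of 10000 expression-matched random lists. Neutrophil genes lay far lower: S100a8, a subunit of the calprotectin complex, averaged 2324 TPM at E12.5 and was listed at 0 at E16.5.

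Among other groups, 14 of 17 measured genes of inflammatory cytokines and NF-kB signalling were higher at E16.5 (median 1.79), including Il1a, which encodes interleukin 1 alpha (141 and 10.1 TPM, 3.68), and the chemokine genes Ccl4 (923 and 125 TPM, 2.87) and Ccl2 (1761 and 400.5 TPM, 2.13). All 13 measured immediate early genes, a list also raised by cell dissociation, were higher (median 1.32), for example Btg2 (719 and 246 TPM) and Jun (135 and 49.1 TPM). Markers of border-associated macrophages, which line the meninges, perivascular spaces and choroid plexus, were also higher in 9 of 11 (median 1.04). Of these, Lyve1, a hyaluronan receptor, averaged 615 and 193 TPM (1.67), Pf4, a chemokine, 4294 and 1905 TPM (1.17), and Mrc1, the mannose receptor, 1552 and 870.2 TPM (0.83). Monocyte markers were lower in 6 of 7 (median -2.98, or -0.28 as a difference of mean log2 values), among them Ccr2, the chemokine receptor of circulating monocytes (15.9 and 75.6 TPM, -2.18), and all 7 neutrophil markers were lower (median -9.40, or -0.87 in the same terms). At E12.5, 4 of 146 cells held 90% of all S100a8, and 3 cells held that share of Ngp, a neutrophil granule gene.

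Of 23 disease-associated microglia genes, 5 were higher and 5 lower (median 0.15). Spp1, which encodes osteopontin, averaged 466 and 75.6 TPM (2.61), with 1 of the 126 E16.5 cells holding 88.3% of it. Lyz2, lysozyme, averaged 891 and 3629 TPM (-2.02), and Lpl, lipoprotein lipase, 71.7 and 277 TPM (-1.94). Cell cycle genes leaned lower, with 1 of 23 higher and 8 lower (median -0.33), and the mitotic cyclin gene Ccnb1 averaged 30.6 and 173 TPM (-2.46). Glycolysis genes were lower in 4 of 11 and higher in 1 (median -0.48), with Pgk1, phosphoglycerate kinase, at 198 and 439.8 TPM. Complement genes were higher in 4 of 9 (median 0.44), C1qa among them (656 and 294 TPM, 1.16), and genes of lysosome and phagocytosis in 4 of 18 (median 0.38), with the protease gene Ctsl at 995 and 444 TPM. Genes of TGF-beta signalling, on which microglial identity depends, were higher in 6 of 10 (median 0.64; Tgfbr2 80.7 and 32.4 TPM), macrophage transcription factors in 6 of 12 (median 0.58; Maf 1017 and 500.1 TPM) and MHC class I genes in 4 of 8 (median 0.54; H2-K1 809 and 391 TPM). Interferon response genes were higher in 7 of 15 and lower in 2, with a median of 0.52 that turned to -0.05 as a difference of mean log2 values. Lipid handling genes had a median of -0.12 (Plin2, a lipid droplet coat gene, 437 and 870.4 TPM), ribosomal protein genes -0.14 and the 5 fetal and imprinted genes -1.0.

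Genes of other brain and blood cells were few among those measured. Astrocyte markers had a median of 2.36 over 3 genes, oligodendrocyte lineage markers 0.45 over 3, neural progenitor markers -2.66 over 2 and neuron markers -0.68 over 2, and the last 3 of these turned to -0.12, 1.89 and 0.14 as differences of mean log2 values. B cell markers had a median of -0.31 over 2 genes, and the single measured marker gave 1.05 for T cells, -2.99 for natural killer cells, 0.69 for endothelial cells and -3.11 for erythroid cells; no dendritic cell or mural cell marker reached the level at which a gene counted as measured. Genes with the largest differences outside the lists included Cd72, a B cell and macrophage surface receptor (121 and 9.66 TPM, 3.52), higher at E16.5, and Anxa1, annexin A1 (2.89 and 292 TPM, -6.23), and Vim, vimentin (26.3 and 220.4 TPM, -3.02), lower at E16.5. Each of the embryonic stages was 1 unbroken run of cell numbers in the titles, so age and preparation cannot be told apart.

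Next, adult whole-brain cells were compared with those of E16.5 in the same way. All 11 measured markers of border-associated macrophages were lower in the adult (median -6.43, or -3.19 as a difference of mean log2 values). F13a1, the A subunit of coagulation factor XIII (chromosome 13, 36867178 to 37050244, minus strand), averaged 0.239 TPM in the adult and 1305 TPM at E16.5 (-10.04). Lyve1 averaged 0.0389 and 615 TPM (-9.21), Ms4a7 0.912 and 533 TPM (-8.13), and Folr2, a folate receptor, was listed at 0 in the adult against 219.9 TPM. Homeostatic genes stood higher, with 11 of 14 higher and 0 lower (median 1.65 against -0.09 over all measured genes). Cst3, which encodes the protease inhibitor cystatin C (chromosome 2, 148871722 to 148875692, minus strand), averaged 36822 and 3054 TPM (3.59), and Tmem119, a microglial surface protein, 658 and 148 TPM (2.14).

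All 23 measured cell cycle genes were lower in the adult (median -2.93, or -0.88 as a difference of mean log2 values), with the mitotic kinase gene Cdk1 at 1.12 and 169 TPM (-6.33) and Top2a, topoisomerase II alpha, at 17.2 and 134 TPM (-2.89). Disease-associated microglia genes were lower in 12 of 23 and higher in 3 (median -1.05, percentile 0.14). Spp1 averaged 0.730 and 466 TPM (-8.08), Igf1, insulin-like growth factor 1, 4.13 and 189 TPM (-5.21), and Apoe, the lipid-carrying apolipoprotein E, 290.3 and 3751 TPM (-3.69). Immediate early genes were higher in 14 of 15 (median 2.30), with Junb at 483 and 34.3 TPM (3.78) and Atf3 at 1618 and 208 TPM (2.95), and inflammatory genes in 11 of 18 (median 1.03), with Tnf, tumour necrosis factor, at 130.3 and 9.66 TPM (3.62) and Nfkbia, the NF-kB inhibitor, at 1722 and 184 TPM (3.22). The genes with the largest differences upward included the heat shock genes Hspa1a (282 and 1.91 TPM, 6.60) and Hspa1b (212 and 0.823 TPM, 6.87).

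Interferon response genes were lower in 12 of 14 in the adult (median -1.80), with Ifitm3, a restriction factor of viral entry, at 18.9 and 344 TPM (-4.12). Glycolysis genes were lower in 10 of 11 (median -1.61; Pkm, pyruvate kinase, 66.4 and 373 TPM) and ribosomal protein genes in 63 of 80 (median -0.90). The 3 measured MHC class II genes were higher (median 2.51), among them H2-DMa, which loads peptides (241 and 79.0 TPM, 1.60). TGF-beta genes were higher in 7 of 11 (median 1.21) and macrophage transcription factors in 5 of 13 (median 0.33), but as differences of mean log2 values these medians were -0.10 and -0.22. Maf, a macrophage transcription factor, averaged 297 and 1017 TPM (-1.77). Lysosome genes had a median of -0.33 (Ctsb, cathepsin B, 932 and 3194 TPM) and lipid genes -0.69 (Plin2 44.0 and 437 TPM). The medians of MHC class I and complement genes, 0.27 and 0.19, were -0.62 and 0.00 as differences of mean log2 values. All 5 neutrophil markers averaged higher in the adult (median 8.01, or 0.12 as a difference of mean log2 values), and 1 of the 221 adult cells held 99.97% of S100a8. The largest adult run of titles held 192 of the 221 cells, so leaving it out kept few. Without it the difference of Pax6 changed from 4.13 to -2.22 and the homeostatic median from 1.65 to 2.33. Of 84 named genes 7 changed direction, Ptprc among them (-0.36 to 0.15).

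Adult cells were also set against E12.5 across the whole span. Homeostatic genes were higher in 13 of 14 (median 2.99), with Siglech at 1462 and 115 TPM (3.66), and cell cycle genes lower in 22 of 23 (median -3.49). Disease-associated microglia genes were lower in 13 of 23 and higher in 7 (median -1.59). Sall1 averaged 88.5 TPM in the adult and 11.0 TPM at E12.5 (2.89), close to the 85.2 TPM of E16.5, while Tmem119 averaged 49.9, 148 and 658 TPM at E12.5, E16.5 and adult.

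The share of cells with a gene was then examined, with exact Clopper-Pearson 95% intervals that cover counting error over cells only. Mki67, a proliferation marker, was at 1 TPM or more in 42.5% of E12.5 cells (62 of 146, 34.3 to 50.9%), 22.2% of E16.5 cells (28 of 126, 15.3 to 30.5%) and 2.71% of adult whole-brain cells (6 of 221, 1.0 to 5.82%). At P7 it was found in 12 of 34 hippocampal, 15 of 44 thalamic and 9 of 32 visual cortex cells. Mrc1 was at 1 TPM or more in 81.5% (74.2 to 87.4%), 94.4% (88.9 to 97.7%) and 6.33% (3.51 to 10.4%) of cells at E12.5, E16.5 and adult. Spp1 was found in 13% (8.02 to 19.6%), 41.3% (32.6 to 50.4%) and 1.81% (0.495 to 4.57%), and Ly6c2, a gene of the gated-out Ly6C antigen, in 5.48% (2.40 to 10.5%), 4.76% (1.77 to 10.1%) and 9.95% (6.34 to 14.7%). Raising the level to 100 TPM, a choice made after seeing the data, changed the shares of Mki67 to 15.8%, 10.3% and 0.905%, of Mrc1 to 58.9%, 59.5% and 3.17% and of Spp1 to 5.48%, 6.35% and 0.452%.

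F13a1 was at 1 TPM or more in 75.3%, 90.5% and 2.26% of E12.5, E16.5 and adult whole-brain cells. P2ry12 was found in 84.2%, 99.2% and 100% and Sall1 in 11%, 39.7% and 48%. Many of the E16.5 cells counted for F13a1 held only a few TPM of it. Some of these had high Sall1, for example 475.78 TPM beside 2.26 TPM of F13a1. At the level of 100 TPM the order of the embryonic ages was the other way round for F13a1, which was present in 76 of 146 E12.5 cells (52.1%), 54 of 126 E16.5 cells (42.9%) and 0 of 221 adult whole-brain cells, which allows a share of up to 1.36%. At this level P2ry12 was present in 44.5%, 61.9% and 93.2% of these cells and Sall1 in 2.74%, 17.5% and 19%. No cell of the 1617 had both F13a1 and Sall1 at 100 TPM or more, although 153 cells had F13a1 and 537 had Sall1; independent placing of both genes within each of the 17 sets would give 18.53. At E16.5 the count was 0 where 9.43 would be independent. Lyve1 and Sall1 likewise shared 0 cells, where 11.2 would be independent within the sets, 7.86 of these at E16.5. Pf4 shared 5 cells with Sall1 and F13a1 shared 6 with Tmem119, where 25.5 and 29.4 would be independent within the sets. Below the level of 100 TPM, which was chosen after seeing the data, some cells held both F13a1 and Sall1. They were at 83.85 and 49.06 TPM in 1 E16.5 cell and at 92.79 and 51.29 TPM in 1 E12.5 cell. Mrc1 overlapped with both: at E16.5 it shared 52 cells with F13a1 (32.1 if independent) and 3 with Sall1 (13.1 if independent), while in the paired-end P14 visual cortex cells 32 had Mrc1 with Sall1 (29.8 if independent). P2ry12 was found beside F13a1 in 31 E12.5 cells (33.8 if independent) and 23 E16.5 cells (33.4 if independent).

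**Figure D1:**
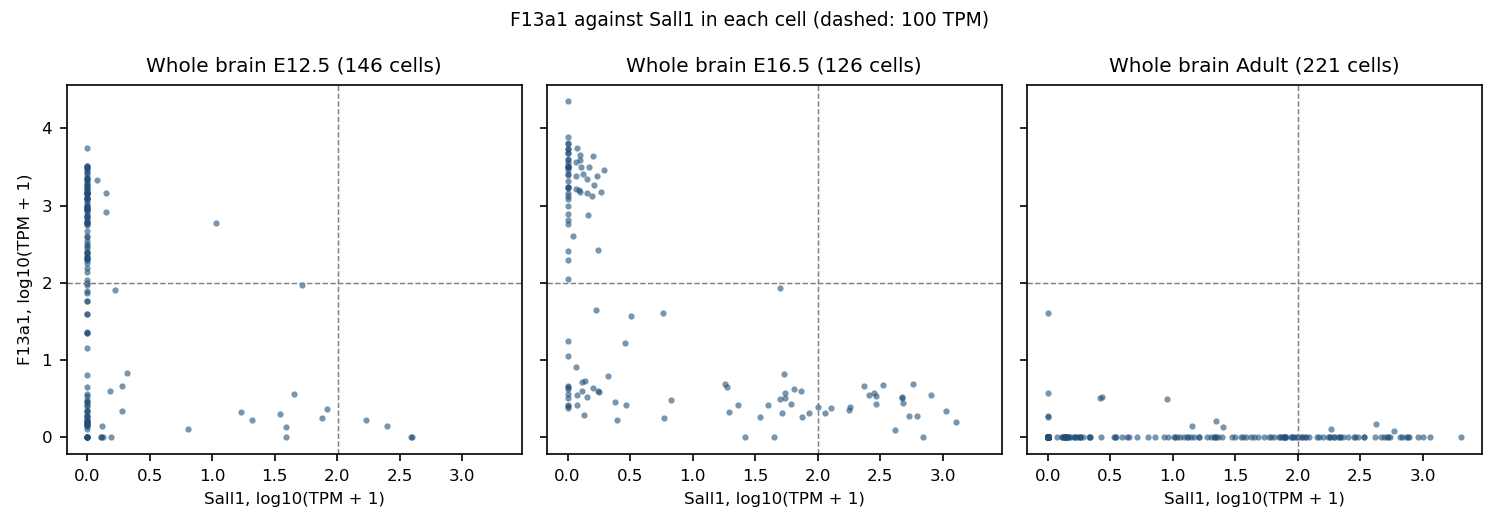
Each point is 1 whole-brain cell at E12.5 (146), E16.5 (126) or adult (221), with log10(TPM + 1) of Sall1 on the x axis and of F13a1 on the y axis, and dashed lines at 100 TPM. The upper right corner, where both genes reach 100 TPM, holds 0 cells at each age.

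To examine changes between the juvenile and the adult brain, adult cells were compared with single-read P14 cells in hippocampus, thalamus and visual cortex, in that order below. Runx1, a transcription factor of haematopoietic and macrophage lineages (chromosome 16, 92601466 to 92826149, minus strand), averaged 120.0, 176 and 184 TPM in the adult and 42.2, 55.6 and 38.2 TPM at P14 (log2 1.49, 1.65 and 2.24). Gpr165, an orphan G protein-coupled receptor, averaged 8.27, 28.2 and 16.4 TPM in the adult and 178, 131 and 173 TPM at P14 (-4.27, -2.18 and -3.32). Crybb1, a crystallin gene, was lower at -2.97, -1.67 and -2.68. Homeostatic genes had medians of -0.29, -0.27 and -0.05, which were 0.06 in hippocampus and 0.02 in visual cortex after median-ratio rescaling and -1.39, -0.75 and -0.37 as differences of mean log2 values. P2ry12 (6326, 4491 and 7074 TPM against 9632, 9973 and 10844 TPM) and Sall1 (157, 219 and 169.7 TPM against 303, 352 and 407 TPM) were lower in all 3 regions. The medians of all measured genes were -0.39, -0.04 and -0.07.

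Cell cycle genes were lower in the adult in 10 of 15, 9 of 15 and 13 of 19 measured members (medians -1.62, -1.01 and -2.15, or -0.19, -0.14 and -0.26 as differences of mean log2 values; -0.75 in hippocampus after rescaling without Calb1, Pax6, Cp and Smco1), with Rrm2 and Top2a lower in each region. Ribosomal protein genes were lower in 39 of 81, 56 of 80 and 38 of 80 (medians -0.54, -0.93 and -0.53), 19 of them in all 3 regions, such as Rpl32 (402, 464 and 422 TPM against 816, 1086 and 941 TPM). Disease-associated microglia genes went both ways, with medians of 0.19, -0.43 and 0.16, which were -0.38 in hippocampus and -0.10 in visual cortex as differences of mean log2 values; Lyz2 was higher in each region (345, 495 and 293 TPM against 81.9, 194 and 59.0 TPM). Apoe averaged 230.3, 906 and 100.2 TPM against 813, 1279.8 and 522 TPM, and in thalamus its difference of -0.50 became 0.32 without the second adult run. The anaphylatoxin receptor genes C3ar1 (320.4, 309 and 288 TPM against 98.1, 141 and 118 TPM) and C5ar1 (121, 138 and 222 TPM against 39.8, 67.0 and 40.6 TPM) were higher in each region, while complement as a list had medians of -0.03, 0.07 and -0.10; rescaling gave 0.33 in hippocampus, rescaling without Calb1, Pax6, Cp and Smco1 gave 0.03 there, and the difference of mean log2 values -0.05 in thalamus.

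Markers of border-associated macrophages differed by region, with medians of 3.35 over 7 genes in hippocampus, 0.05 over 4 in thalamus and -1.92 over 5 in visual cortex, where the difference of mean log2 values was 0.04 (0.76 in hippocampus). In adult hippocampus, 10 of 66 cells had F13a1 at 100 TPM or more (mean 66.1 TPM), all of them in 1 of its 2 title runs. Interferon response genes had medians of 1.67, 1.12 and -1.13, which were 0.16, 0.10 and -0.10 as differences of mean log2 values. Among macrophage transcription factors, Cebpa and Runx1 were higher and Bhlhe41, Cebpb and Sall1 lower in all 3 regions. Bhlhe41 averaged 879, 576 and 332 TPM against 1808, 1206 and 2854 TPM, but against paired-end P14 cells of visual cortex it was higher (1.88). Lysosome genes had medians of -0.53, -0.27 and -0.03 and lipid genes -0.83, -0.50 and -0.38; rescaling turned the lysosome median of visual cortex to 0.04. Srgn, the proteoglycan serglycin, ranked first among genes higher in each region (4.04, 3.03 and 3.76), but without the second adult hippocampal run its hippocampal value was -0.35.

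**Figure D2:**
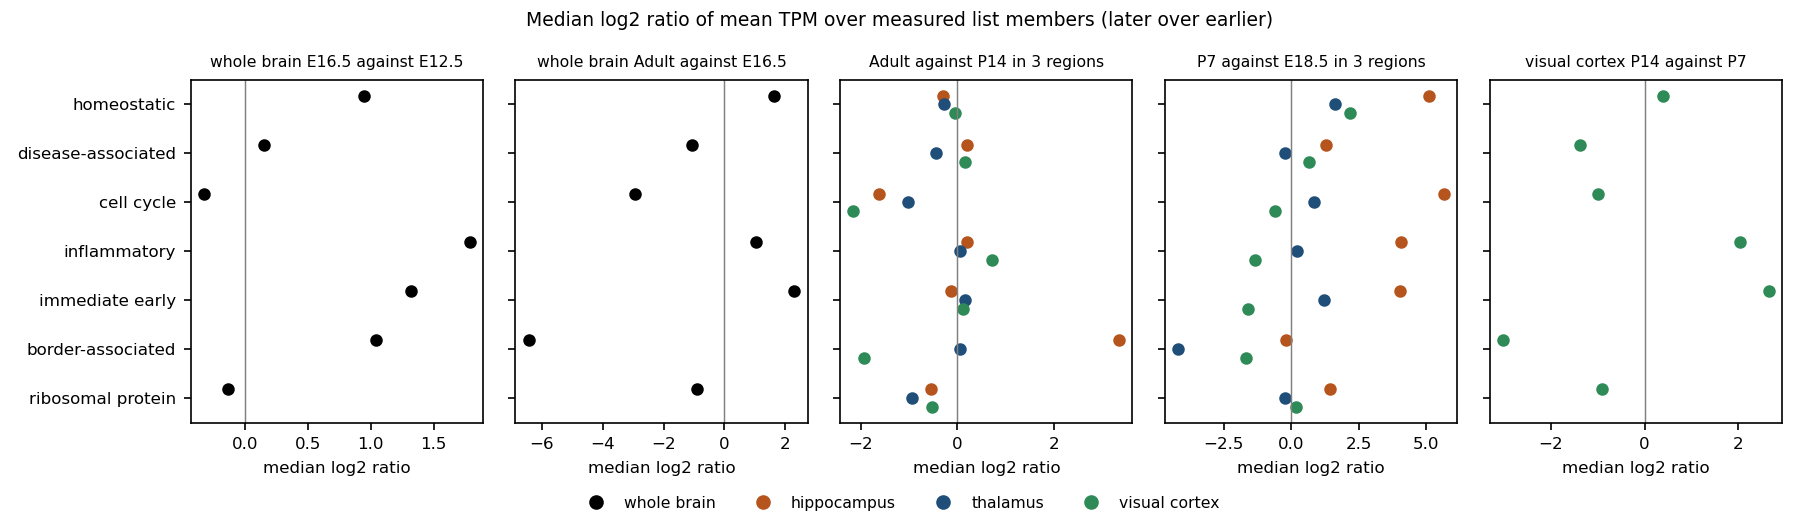
Each point is the median log2 ratio of mean TPM over the measured members of a gene list, later age over earlier age, in 5 panels of age comparisons whose x axes differ; black is whole brain, orange hippocampus, blue thalamus and green visual cortex, and the line marks 0. Cell cycle genes lie at -2.93 for adult whole brain over E16.5 and homeostatic genes at 1.63 to 5.10 for P7 over E18.5.

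Perinatal change was examined by comparing P7 with E18.5 cells, all paired-end, in hippocampus, thalamus and visual cortex. Homeostatic genes stood higher at P7 in 14, 13 and 12 of 14 members (medians 5.10, 1.63 and 2.17, or 2.78, 0.81 and 1.98 after median-ratio rescaling), 11 of them in all 3 regions. P2ry12 averaged 7672, 6659.9 and 9058 TPM at P7 and 64.1, 1325 and 455 TPM at E18.5 (6.88, 2.33 and 4.31). Olfml3, a secreted olfactomedin-like protein, averaged 868, 1129.6 and 1116 TPM against 20.8, 258 and 299 TPM. Itgam, which encodes the CD11b chain of the sort, averaged 508, 443 and 313 TPM against 0.232, 58.3 and 24.0 TPM. Medians over all measured genes were 3.83, 0.79 and 0.10, the last -0.08 after rescaling. Of the 21 hippocampal E18.5 cells, 20 held fewer than 1000 genes and their median mitochondrial share was 48.5%, against 4.35% at P7, so hippocampal values are given for completeness. At E18.5, 16 of 50 thalamic and 6 of 22 visual cortex cells held fewer than 1000 genes, with median mitochondrial shares of 10.4% and 4.57% against 4.61% and 4.81% at P7.

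In thalamus and visual cortex, Sall1 averaged 249 and 308 TPM at P7 against 77.4 and 24.5 TPM (1.67 and 3.60), and Mertk, a phagocytic receptor, 199 and 421 TPM against 56.8 and 71.4 TPM. Tgfbr1, a TGF-beta receptor chain, averaged 274 and 99.5 TPM against 72.9 and 48.8 TPM. Complement genes were higher in 7 of 8 in thalamus and 4 of 8 in visual cortex (medians 1.42 and 0.52), and lysosome genes in 11 of 18 and 13 of 18 (0.67 and 0.79), though rescaling took the thalamic medians to 0.59 and -0.15. Markers of border-associated macrophages were lower in 9 of 9 and 6 of 10 (medians -4.19 and -1.66, or -0.43 and -0.75 as differences of mean log2 values). In thalamus, 4 of 50 E18.5 cells held 90% of F13a1. Mean Cd163, Folr2 and Pf4 were lower in all 3 regions, but in hippocampus Pf4 was at 1 TPM or more in 1 of 21 E18.5 cells. At 100 TPM its share there was 8.82% at P7 and 4.76% at E18.5. Cell cycle genes had medians of 5.65 in hippocampus, 0.85 in thalamus and -0.60 in visual cortex, and the thalamic one was 0.04 after rescaling and 0.14 as a difference of mean log2 values. Disease-associated microglia genes had medians of 1.29, -0.24 and 0.64, and rescaling turned the hippocampal one to -1.03. Restricting to cells with 1000 genes or more left a homeostatic median of 2.16 in visual cortex (28 and 16 cells). Each P7 and E18.5 group was 1 run of titles, so age and run cannot be told apart. In visual cortex Xist was found in 9.09% of E18.5 and 71.9% of P7 cells, and Ddx3y in 27.3% and 0%. In thalamus Xist was found in 40% and 84.1%, and Ddx3y in 16% and 0%. Kdm5d, also Y-linked, was found in 31.8% and 34.4% in visual cortex. Sex may therefore differ between these ages too. Median-ratio rescaling moved the mean over regions of the all-gene median by -0.73.

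Between P7 and P14, the paired-end visual cortex cells (32 and 150) could be compared within 1 layout. Disease-associated microglia genes were lower at P14 in 17 of 22 and higher in 1 (median -1.39). Spp1 (chromosome 5, 104435118 to 104441050, plus strand) averaged 4169 TPM at P7, where 9 of 32 cells had 100 TPM or more and 1 cell held 70.1% of the total, and was listed at 0 in all 150 P14 cells, which allows a share of up to 2.0%. Igf1 averaged 7.64 TPM at P14 and 184 TPM at P7 (-4.42), Lpl 44.9 and 201 TPM (-2.13) and Plin2 128 and 859 TPM (-2.74). Inflammatory genes were higher in 13 of 17 (median 2.04), led by Il1a (chromosome 2, 129299610 to 129309972, minus strand) at 352 and 0.284 TPM (8.10). At P7, Il1a averaged 26.8 TPM in hippocampus and 86.0 TPM in thalamus, so the visual cortex value was the lowest. In single-read P14 visual cortex cells it averaged 115 TPM. The inflammatory list was also higher in paired-end than in single-read P14 cells, as given below. Immediate early genes were higher in 13 of 13 (median 2.65), with Btg2 at 4229 and 454 TPM (3.22) and Fosb at 91.3 and 5.09 TPM (3.92). The P7 cells were 1 run of titles, so age and run cannot be told apart.

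Homeostatic genes were higher at P14 in 5 of 14 and lower in 1 (median 0.40, or -0.23 after median-ratio rescaling), among them Selplg, P-selectin ligand (761 and 288 TPM, 1.40), and Tmem119 (693 and 303 TPM, 1.19). All 8 border-associated macrophage markers were lower (median -3.02, or -0.38 as a difference of mean log2 values; 1 of 32 P7 cells held 99.97% of F13a1), including Mrc1 (212 and 714 TPM, -1.75) and Stab1, a scavenger receptor (397 and 1233 TPM, -1.63). Cell cycle genes were lower in 13 of 23 and higher in 7 (median -0.99; Top2a 22.5 and 78.5 TPM), and ribosomal protein genes lower in 54 of 79 (median -0.90). The classical MHC class I genes H2-D1 (1243 and 204 TPM, 2.60) and H2-K1 (2991 and 745 TPM, 2.0) were higher, while the list had a median of 0.15, or -0.46 after rescaling. TGF-beta genes were higher in 7 of 10 (median 1.0), with Tgfbr1 at 428 and 99.5 TPM. Over all measured genes the median was 0.91, and rescaling moved it by -0.60. Xist was found in 36% of these P14 and 71.9% of the P7 cells, and Ddx3y in 26.7% and 0%. Sex may therefore differ as well as age and run.

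A2M hippocampal cells (83, paired-end) were compared with adult hippocampal cells (66, single-read). Because layout differs throughout, P7 hippocampal cells (34, paired-end) served as a second reference. Paired-end against single-read P14 visual cortex cells served as a control. Sex-linked genes differed between these sets. Xist was found in 0 of 83 A2M cells, 57.6% of adult and 73.5% of P7 cells. The Y-linked Ddx3y was found in 36.1%, 10.6% and 0%. Kdm5d and Uty, also Y-linked, went the other way, at 6.02% and 4.82% in A2M and 33.3% and 48.5% in adult cells. In the control sets Xist was in 36% of paired-end and 83.3% of single-read cells, with Y-linked genes both ways. Sex, layout and group cannot be told apart here. Hspb1, a small heat shock protein (chromosome 5, 135887919 to 135889563, plus strand), averaged 2083 TPM in A2M cells, 1.08 TPM in adult cells (9.97) and was listed at 0 at P7; 26 of 83 A2M cells had 100 TPM or more. The MHC class II list was higher in 6 of 6 against adult (median 4.92) and 4 of 6 against P7 (median 4.68), or 1.04 and 1.17 as differences of mean log2 values, with Cd74, the invariant chain, at 383, 26.3 and 37.0 TPM in A2M, adult and P7. The complement genes C1qa (6662, 469 and 879.5 TPM) and C1qc (8741, 633 and 1869.8 TPM) were higher against both, although complement as a list had medians of -0.06 and 0.17, the former 0.08 after rescaling and 0.95 as a difference of mean log2 values. Disease-associated microglia genes were higher in 14 of 22 against each reference (medians 1.25 and 0.93, the former 0.72 after rescaling without Calb1, Pax6, Cp and Smco1; 0.07 in the layout control, or -0.15 there as a difference of mean log2 values), including Lyz2 at 1746, 345 and 444 TPM.

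Inflammatory genes were higher in 15 of 18 against both (medians 1.84 and 3.23), but also in 15 of 18 in the layout control (median 1.42). Nfkbia averaged 4786 TPM in A2M and 168 TPM in adult cells (4.82), and Cebpb, a transcription factor of the acute phase response, 298, 2.54 and 0.446 TPM in A2M, adult and P7. Immediate early genes had medians of 2.14 and 2.66 (control 0.17), with Junb at 2592, 40.2 and 108 TPM. Cell cycle genes had medians of -1.95 and -4.79 (control 0.11), which were -0.49 and -1.05 (control -0.06) as differences of mean log2 values; Top2a averaged 0.0829 TPM in A2M and 238 TPM at P7. Homeostatic genes had medians of 0.19 and 0.63 (control -0.13; 2.34 and 2.47 as differences of mean log2 values; against adult -0.16 without cells with Calb1 at 100000 TPM or more), with Cst3 at 91668, 17977 and 8135 TPM and Sall1 at 58.6, 157 and 259 TPM. Ribosomal protein genes changed direction with the reference (medians 0.34 and -1.14). Bhlhe41 averaged 8.27 TPM in A2M and 879 TPM in adult cells, and in the control 89.7 TPM in paired-end and 2854 TPM in single-read cells. Calb1, a neuronal calcium-binding protein gene, was listed at 0 in A2M cells and averaged 138102 TPM in adult cells. With P7 as reference the all-gene median moved by 0.37.

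To examine regional differences, the 3 regions were compared within each age. At P14 the median absolute log2 difference over genes at 50 TPM or more was 0.45 to 0.51 between regions. Title runs, which hold fewer cells, differed by 0.73 to 1.13 within a region and by 0.62 to 1.28 between regions. In the adult it was 0.73 to 0.89 between regions, 1.0 to 2.22 between runs of a region and 1.01 to 2.60 between runs of different regions. At P7 it was 0.93 to 1.35 and at E18.5 1.19 to 5.32, with 1 run per group. Among genes that met the level rule and name filter for named genes, some were at least 1.5-fold above both other regions at both P14 and adult. They numbered 7 in hippocampus, 17 in thalamus and 7 in visual cortex. How many run differences alone would give was not examined. Tsen15, a subunit of the tRNA splicing endonuclease (chromosome 1, 152370735 to 152386688), averaged 67.3 TPM in P14 thalamus against 2.40 TPM in hippocampus and 4.81 TPM in visual cortex, and 131 TPM against 4.83 and 12.8 TPM in the adult. Il6st, the shared signalling chain of interleukin 6 receptors, averaged 103 TPM in P14 thalamus against 49.7 and 36.8 TPM, and 126 TPM against 35.2 and 60.2 TPM in the adult. Btk, a tyrosine kinase of myeloid and B cells, was highest in hippocampus (116 TPM at P14 and 181 TPM in the adult), but its runs overlapped between regions. Cd82, a tetraspanin, averaged 148 TPM in P14 visual cortex against 51.3 and 41.7 TPM, and 123 TPM against 61.6 and 40.2 TPM in the adult, and its runs overlapped between regions too (21.6 to 236 TPM in P14 visual cortex against up to 95.1 TPM in hippocampus). At the ages not used to pick these genes the regions often ranked otherwise: at P7 Il6st was higher in hippocampus (65.2 TPM) than in thalamus (36.4 TPM) and Cd82 higher in thalamus (89.7 TPM) than in visual cortex (45.0 TPM), while Tsen15 was highest in thalamus (30.1 TPM). At E18.5 Tsen15 was listed at 0 in thalamus and averaged 39.0 TPM in visual cortex, Btk was listed at 0 in hippocampus and averaged 79.5 TPM in thalamus, and Cd82 was lowest in visual cortex (20.8 TPM).

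**Figure D3:**
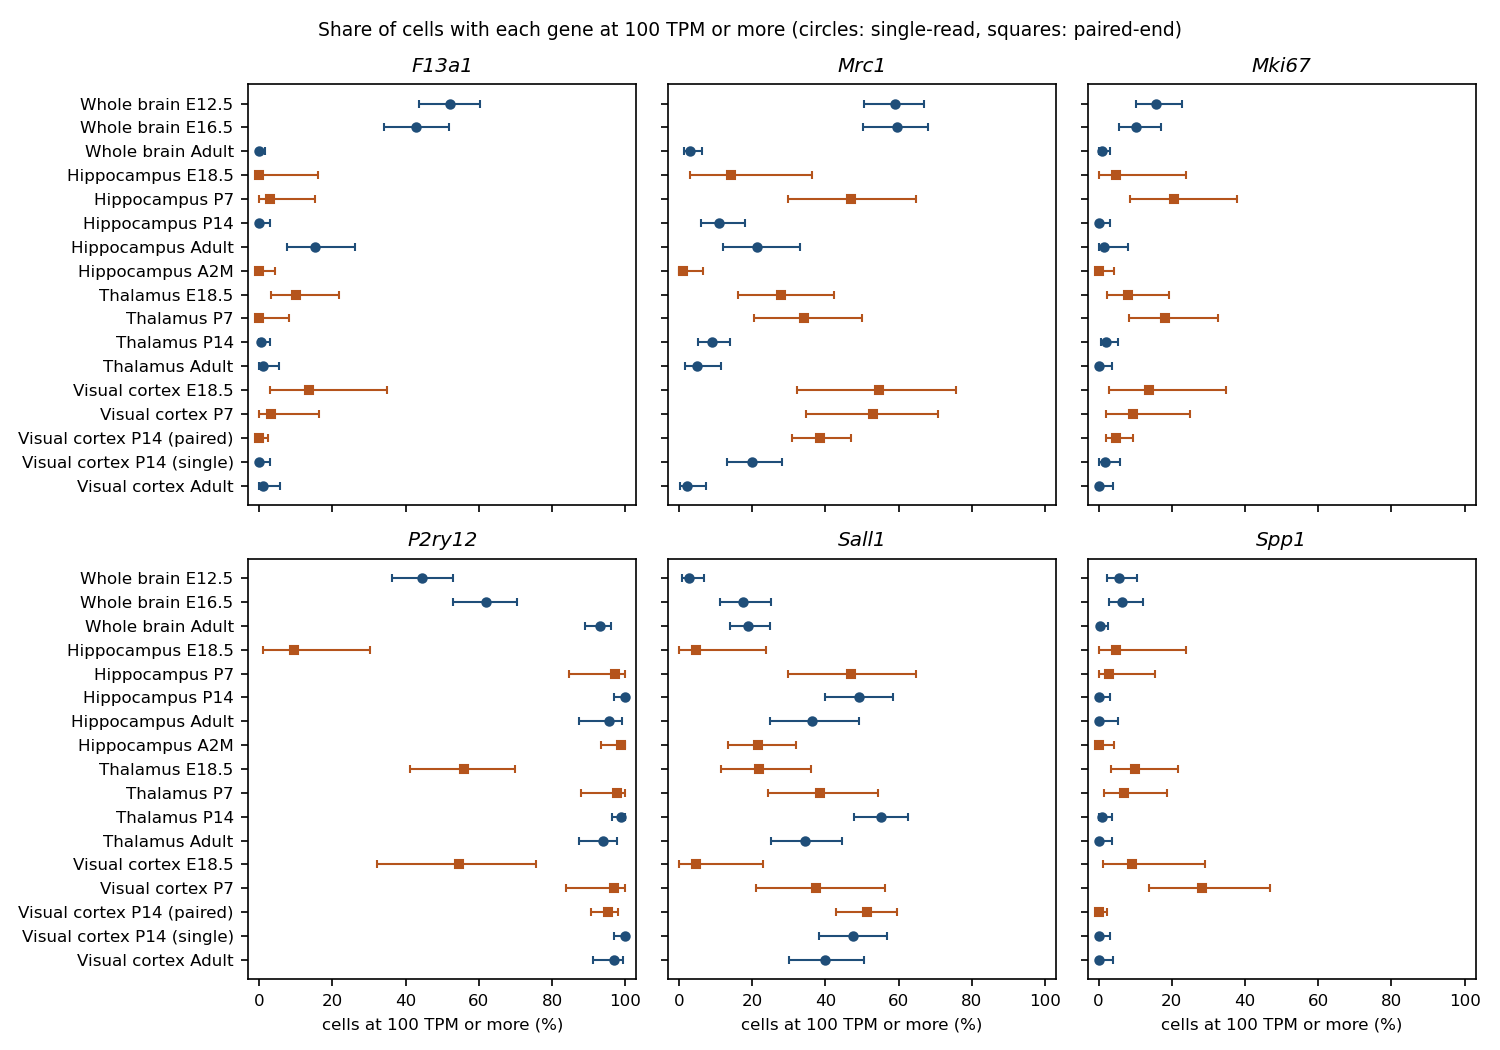
Each panel gives 1 gene, with the percent of cells at 100 TPM or more on the x axis and the 17 sets of cells on the y axis; blue circles are single-read sets, orange squares paired-end sets, and bars exact 95% intervals over cells. F13a1 stands at 52.1% of E12.5 and 42.9% of E16.5 cells (75.3% and 90.5% at 1 TPM or more), and P2ry12 at 44.5%, 61.9% and 93.2% of whole-brain cells at E12.5, E16.5 and adult.

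The genes of the sort and of sex were also read in every set. Ptprc, which encodes CD45, was at 1 TPM or more in 43.8 to 92.9% of cells of a set, Emr1, which encodes F4/80, in 38.9 to 94.4% and Itgam in 40.9 to 99.2%, leaving out hippocampal E18.5 cells, where Ptprc was found in 0 of 21 cells (a share of up to 14.3% is allowed), Emr1 in 4.76% and Itgam in 9.52%. As a list in whole brain, the 4 measured sort genes had medians of 0.05 for E16.5 over E12.5 and -0.09 for adult over E16.5, each of which changed sign with rescaling (-0.10 and 0.01). Sex genes, 5 measured in whole brain, had medians of 0.65 and -1.34, the former -0.07 as a difference of mean log2 values; without the largest adult run Eif2s3y, the member at the second median, was at 1.37 and Ddx3y at 1.03. Xist, the X inactivation transcript, was found in 0 of 83 A2M cells, which allows a share of up to 3.61%, while the Y-linked Ddx3y was found in 36.1%. At P7, Ddx3y was found in 0 of 34, 44 and 32 cells of hippocampus, thalamus and visual cortex, which allows shares of up to 8.82%, 6.82% and 9.38%, with Xist in 73.5%, 84.1% and 71.9%; Kdm5d, also Y-linked, was found there in 32.4%, 34.1% and 34.4%.

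Clustering of all cells gave 13 clusters, of which 9 were microglia-like by markers fixed beforehand. The name is weakest for 1 of these, with 70 cells (12 of them among the 21 of hippocampal E18.5), where 4 of 12 microglia markers were seen, mitochondrial genes such as mt-Atp6 led and cells held a median of 0.489 times the genes of their set. The other 4, with 350 of 1617 cells (21.6%, 19.7 to 23.7%), stayed unnamed. Of these, a cluster of 128 cells, 122 of them from E12.5, was led by Emb, S100a8, Cd44 and Lgals3, and a cluster of 104 cells, 89 of them from E16.5, by Lyve1, Fcna, Cd163, Ms4a7, Pf4 and F13a1. A further cluster of 85 cells, 84 of them single-read, was led by Pax6, Calb1, Cp and Smco1. The last, of 33 cells, had a median of 369 genes per cell. Unnamed does not mean without microglia genes. The clusters of 128, 104 and 85 cells had 8, 10 and 12 of the 12 microglia markers seen. The cluster of 85 cells stayed unnamed because Pax6, listed as a neural progenitor marker, was among its leading genes. Cluster sizes were not compared between ages, since several clusters came mostly from 1 set.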

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

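The tests of border-associated macrophage genes in this part were chosen after the result was seen, and the differences between regions were not tested, since each region and age is 1 sample.

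Several lists had medians of opposite sign in different regions. From P14 to adult, interferon response genes had medians of 1.67 in hippocampus, 1.12 in thalamus and -1.13 in visual cortex (0.16, 0.10 and -0.10 as differences of mean log2 values), and border-associated macrophage markers 3.35 in hippocampus and -1.92 in visual cortex, where the difference of mean log2 values gave 0.04. From E18.5 to P7, cell cycle genes had medians of 5.65 in hippocampus, 0.85 in thalamus and -0.60 in visual cortex, and immediate early genes 4.01, 1.21 and -1.62. Over the same ages inflammatory genes had medians of 4.05, 0.22 and -1.36, glycolysis genes 4.60, 0.17 and -0.90, and interferon response genes 3.29, -1.02 and -3.79; after median-ratio rescaling the thalamic medians of the inflammatory and glycolysis lists were -0.59 and -0.65, and the latter was -0.15 as a difference of mean log2 values. Rescaling also brought the thalamic cell cycle and immediate early medians to 0.04 and 0.39. All hippocampal E18.5 values come from 21 cells with a median of 372 genes.

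The border-associated macrophage markers high in adult hippocampus included F13a1, at 100 TPM or more in 10 cells, all in the first of the 2 hippocampal title runs. Mrc1 reached this level in 14 cells, 10 of them the same, and Lyve1 in 1. Pf4 reached it in 10 cells, of which 0 had Sall1 at that level (3.64 if independent). Of the 10 F13a1 cells, 0 had Sall1 and 0 had Tmem119 at that level (3.64 and 4.85 if independent). P2ry12 was at that level in 9 of them (9.55 if independent). The F13a1 cells held a median of 1428.5 genes, against 2934 in the second run, so a missing gene says little. The cells behind the remaining markers are not described here. At 1 TPM or more, F13a1 was also in 34.7% of adult visual cortex and 15.2% of adult thalamus cells, against 0% and 1.05% at P14. A candidate explanation is that border-associated macrophages, which the sort gate takes in, were captured in the first hippocampal run. Of the 10 F13a1 cells, 80% also had Calb1 at 100000 TPM or more, as did 14 of the 23 cells of the run. Those wells stand apart technically, and this explanation stays open. Another candidate is reads from libraries with neighbouring titles, which are those of E16.5. Only 1 gene was high at E16.5 and not at E12.5. It was found in 0% of the cells of the run, against 15.4% in the second adult visual cortex run, but 1 gene cannot decide this. Genes high at both embryonic ages, 6 of them, were above 0 in 47.8% of gene and cell pairs of the run. Their median level was 11.8% of that at E16.5. The highest values among the other adult runs compared were 38.2% and 3.06%. By their levels, the border-associated macrophage markers F13a1 and Lyve1 meet the rule for these 6 genes. The high values of the run therefore restate in part the pattern under question. They cannot tell carried-over reads from cells of the run that hold these genes. In the matching case, the visual cortex adult run beside E12.5, 25.3% of gene and cell pairs of 17 E12.5 genes were above 0, which is 1.85 times the next adult run and does not settle it either; age and region of the animal, which the design names, were not tested.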

How the results depend on the processing

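The settings that left out Calb1-high cells, 4 abundant genes, hippocampus or a pair of adult runs, and the 100 TPM level, were chosen after seeing the data, and the cause of a shift was not tested. No paired analysis was possible because the result comes from no test and the replicate numbers only count cells. Homeostatic and cell cycle medians kept their sign in whole brain and, as means over regions, in adult against P14: homeostatic medians ranged from 0.79 to 1.80 for E16.5 against E12.5, 1.53 to 2.92 for adult against E16.5 and -0.84 to -0.01 for adult against P14, and cell cycle medians from -0.51 to -0.30, -3.40 to -0.88 and -2.01 to -0.20. As differences of mean log2 values, homeostatic medians were 1.80 (E16.5 against E12.5), 2.92 (adult against E16.5), -0.84 (adult against P14), 4.70 (P7 against E18.5) and 1.16 (P14 against P7 in visual cortex), cell cycle medians -0.88, -0.20, 0.34 and -0.38 for the last 4 of these, and the disease-associated median -0.64 in visual cortex. A pseudocount of 10 TPM gave cell cycle medians of -1.74 for adult against E16.5, -0.73 for adult against P14 and 1.02 for P7 against E18.5, and one of 0.1 TPM gave 2.74 for the last. Median-ratio rescaling gave homeostatic, disease-associated and cell cycle medians of 1.86, -0.55 and 1.21 for P7 against E18.5, and -0.23 and -2.01 for the homeostatic and disease-associated lists in visual cortex. For P7 against E18.5, thalamus and visual cortex alone gave 1.90 (homeostatic) and 0.13 (cell cycle), and cells with 1000 genes or more 1.64 (disease-associated). The last is a mean over regions that includes hippocampus, where 1 E18.5 cell was left. Without the largest adult whole-brain run the homeostatic median was 2.33, and with P7 in place of adult hippocampus the A2M cell cycle median was -4.79.

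Several settings moved the all-gene median by more than 0.1, and not all of them are listed here. Rescaling moved it by -0.14 for E16.5 against E12.5 and by 0.14 for adult against P14. Differences of mean log2 values moved it by -0.24 and -0.21 in the whole-brain comparisons, -1.31 for P7 against E18.5 and -0.73 in visual cortex. Without the largest adult whole-brain run it moved by -0.38 and without the second adult hippocampal run by -0.41. For P7 against E18.5, pseudocounts of 0.1 and 10 TPM moved it by 0.93 and -0.87, and thalamus and visual cortex alone by -1.13. Under rescaling, 24 of the 39 genes named for P7 against E18.5 kept their direction, including P2ry12, while Emr1 in thalamus changed to -0.19. Between regions the difference of mean log2 values gave 0.55 at P7 and 1.60 at E18.5. A resolution of 2 put 17.6% of cells outside the microglia-like clusters.

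Shares depended on the level. Mki67 was above 0 TPM in 56.8%, 48.4% and 8.60% of cells at E12.5, E16.5 and adult, at 10 TPM in 32.9% at E12.5, and at 100 TPM in 15.8%, 10.3% and 0.905%. Mrc1 was above 0 in 91.1% and 100% at E12.5 and E16.5, at 10 TPM in 64.4% and 65.1%, and at 100 TPM in 58.9%, 59.5% and, in the adult, 3.17%. Spp1 reached 10 TPM in 6.85% and 11.9% at E12.5 and E16.5, and 100 TPM in 5.48%, 6.35% and, in the adult, 0.452%. Ly6c2 reached 10 TPM in 0% at E16.5 and 0.905% in the adult, and 100 TPM in 2.05% at E12.5, 0% at E16.5 and 0.452% in the adult. Over all sets, 187 shares at other settings stayed within the counting interval and 85 left it. Unknown read depth limits what a value of 0 in a cell can show.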

Other observations

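The tests of Calb1 and its companions and of homeostatic genes at P7 in this part were chosen after the result was seen, and the other values are descriptions.

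Spp1 and Igf1, both named for disease-associated microglia, overlapped in some sets. At 100 TPM or more, both genes were found in 7 of 146 E12.5 cells (3.23 if independent), 6 of 126 E16.5 cells (2.29 if independent), 4 of 32 visual cortex P7 cells (1.97 if independent) and 2 of 22 visual cortex E18.5 cells (0.364 if independent). In thalamus at E18.5, 1 cell had both (1.1 if independent), and hippocampus at E18.5 and hippocampus and thalamus at P7 had 0 such cells, with at most 3 cells for either gene. Over all sets 20 cells had both, where 9.11 would be independent within the sets. Mrc1 reached 100 TPM in 16 of 34, 15 of 44 and 17 of 32 P7 cells of hippocampus, thalamus and visual cortex, and all of these cells also had P2ry12 at that level, where 15.5, 14.7 and 16.47 would be independent, since P2ry12 reached that level in nearly every P7 cell. Sex-linked genes differed between sets. Eif2s3y, a Y-linked gene, was found in 0 of 120 single-read P14 visual cortex cells, which allows a share of up to 2.50%. It was in 22.0% of the paired-end ones, with Xist in 83.3% and 36.0%. Other Y-linked genes were found in both: Ddx3y in 17.5% and 26.7%, Kdm5d in 70.8% and 58.0% and Uty in 48.3% and 51.3%. These genes do not settle the sex of the cells.

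Calb1, Pax6, Cp and Smco1 reached very high levels in single-read sets, but levels differed between title runs. Cp and Smco1 averaged 2.49 and 28.0 TPM in an adult whole-brain run of 28 cells. In the second adult visual cortex run they averaged 35.5 and 81.3 TPM. In P14 visual cortex, Calb1 averaged 23925 TPM in single-read cells and was listed at 0 in paired-end cells, with 0% of the 150 paired-end cells at 1 TPM or more, which argues against expression in macrophages of that age and region. A sequence added to each single-read well in a fixed amount could account for it and would make Calb1 higher in cells with fewer genes. The median Spearman correlation of Calb1 with genes detected, across cells, was -0.142 over 9 single-read sets (range -0.517 to 0.277). It was -0.159 for Pax6, -0.256 for Cp and -0.225 for Smco1 against 0.177 for P2ry12 and 0.199 for Actb. The Calb1 value is weaker than the test asked for. Its sign cannot decide, since a large share of Calb1 lowers the other genes of a cell whatever its source. Mean Calb1 was 503 TPM in an adult whole-brain run of 28 cells and 361020 TPM in the first adult hippocampal run. In the first adult visual cortex run Calb1 averaged 108480 TPM, although median genes were alike (3573 there, 3747 in the 28-cell run). Pax6 averaged 234 TPM in the first adult hippocampal run. In the third adult visual cortex run Pax6 averaged 87743 TPM, beside 23198 TPM of Calb1. These values argue against 1 fixed amount and mix in every single-read well. An added sequence that varied between runs was not tested and stays open. Over the 9 single-read sets, 59 cells had 100000 TPM or more of Calb1, which lowers every other gene of the cell in TPM.

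Homeostatic genes were higher at P7 than at E18.5, and E18.5 wells with little RNA are a possible explanation, given the 372 genes of the median hippocampal E18.5 cell. With cells of 1000 genes or more, the homeostatic median was still 1.37 in thalamus (42 and 34 cells) and 2.16 in visual cortex (28 and 16 cells), which argues against low RNA as the whole cause there. In hippocampus 1 E18.5 cell was left, so nothing can be said. Age and title run cannot be told apart, and age stays open as untested.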
